A study of Rattus norvegicus with 4 samples.

How the data were processed

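Single-cell RNA sequencing was carried out on cells of the abdominal midline fascia of rats with dysentery, with or without acupuncture. There were 4 libraries in 2 groups, with 2 libraries per group. Per the labels, the tissue was digested with collagenase and elastase, dead cells and red blood cells were removed, and libraries were made with droplet chemistry that counts molecules at the 3' end of transcripts. Per the labels and the file headers, the authors made the matrices with Cell Ranger 6.0.1, which aligns with STAR. The submitters' notes name the builds mRatBN7.2 and GRCh38.p13 without giving the role of either, and every gene identifier was a rat Ensembl identifier. The deposited matrices hold raw UMI counts per gene and cell, with no normalization. The deposited barcode and feature lists hold other content than measurements, namely the names of the matrix columns and of the matrix rows. The lowest total per deposited cell was 500 UMIs in 3 libraries and 502 in the other.

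The libraries were grouped by their titles. The descriptions and the design text give the same groups as the titles, but the treatment field of each of the 4 libraries names the opposite group. Every direction given here rests on the titles. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these libraries. No batch or date is given in the labels. Checks of library pairs found no duplicated library.

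The matrices share 30560 gene rows, of which 7162 have only an identifier, and 236 symbols stand on more than 1 row. Rows were kept apart by identifier and named by symbol. None of the identifiers could be matched to the reference tables at hand (0 matches), so no coordinates are given. Cells with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs over 13 mitochondrial genes were kept. Scrublet scores, from scanpy 1.11.5, were computed per library, and the highest-scoring cells were removed at a rate of 0.8% per 1000 cells. That left 32397 of 38282 deposited cells. Cells were normalised, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with the Leiden method at resolution 1 (igraph 0.11.9). Clusters were named from fixed marker lists when at least 3 markers were detected in 10% of cells or more at 2-fold or more over other cells (10 CPM added). Of the 31 clusters, 4 stayed unnamed. Names end in "-like" because they rest on markers alone. Cd34 and Pdgfra, the usual markers of telocytes (interstitial cells with long thin processes), are shared with fascia fibroblasts, so these formed 1 class.

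UMI counts were summed per library and class, and the library was the replicate. Classes with at least 30 cells in every library were tested. The edgeR 4.0.16 quasi-likelihood test was run on TMM-scaled sums, with genes kept by filterByExpr at its minimum count of 10 and Benjamini-Hochberg adjustment within each class at a threshold of 0.05. Log2 fold changes are acupuncture minus dysentery with the standard error (SE) of the fit, and means are in CPM (counts scaled to a common library total) with the standard deviation (SD) over 2 libraries. The difference in change between the fibroblast/telocyte-like and macrophage-like classes was tested by an interaction term with library as a block. Class shares were tested with edgeR on cell numbers. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, with a two-sided exact permutation test whose smallest possible p is 1 in 3. Their 95% Clopper-Pearson intervals, and floors of 3 counts over a group, cover counting error only.

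There were 32 gene lists, with 733 genes, of which 56 had no row under their symbol and 17 stood on shared symbols. They cover prostaglandin synthesis and response, M2 macrophages, M1 macrophages, inflammatory cytokines and chemokines, the NF-kB response, immediate early and dissociation stress genes, heat shock, the glucocorticoid response, the interferon response, and acute phase, complement and antimicrobial genes. They also cover collagens and fibrillar matrix, matrix proteases and inhibitors, mechanical stretch and YAP/TEAD targets, tissue niche signals, signals from stroma to macrophages, antigen presentation, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, the cell cycle, and lipid handling and lysosome. The last 11 lists hold markers of other cells, namely platelets and erythrocytes, adipocytes, keratinocytes, skeletal muscle, mast cells, neutrophils, T cells, B cells, macrophages, vascular endothelium and fibroblasts. Each was tested with camera from limma 3.58.1 (prior count 2, preset correlation 0.01), adjusted over the lists of a class. With an estimated correlation, camera bases its p-values on the few libraries rather than on the number of genes. Hardly any list could pass that alternative, whatever its correlation. The groups, tests, lists, marker genes and rule for named genes were fixed before the data were examined. In the 2 main classes the rule named 17 fixed genes, the 8 largest rises and 8 largest falls past the threshold (at least 10 CPM in the higher group, groups separated), and up to 3 members of each list. In other classes it named the 3 largest rises and falls. Genes known only by an identifier or placeholder were counted but not named.

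Alternatives were DESeq2 1.42.0, RLE size factors, no count filter, a replicate block, each library left out in turn, a mitochondrial limit of 10%, doublets kept, Leiden resolutions 0.5 and 2, components centred per library, sums thinned to the smallest library, an estimated correlation between genes, TMM on cell numbers, and thinning of cells to 1000 UMIs or none. Alternatives chosen after seeing the data left out shallow fibroblast clusters, left out a macrophage cluster from mostly 1 library, joined an unnamed cluster to the dendritic cell-like class, or used cells other than fibroblasts as the denominator. The test was also run on simulated data from these counts with 200 changed genes. With edgeR's trended spread, 87.9% of 4-fold changes were recovered in both main classes. For 2-fold changes the share recovered was 68.7% in fibroblast/telocyte-like and 32.8% in macrophage-like cells, and false calls made up 5.47% and 2.38% of calls. When each gene kept its own spread, false calls rose to 19.0% and 15.0%. Work was done in Python 3.11.15 and R 4.3.3.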

Results

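RNA of single cells from the abdominal midline fascia was measured in 4 libraries, 2 from dysenteric rats given acupuncture and 2 from dysenteric rats without it. The acupuncture libraries held 70499776 and 93897006 UMIs in 8930 and 10060 cells, and the dysentery libraries 53066666 and 79461544 UMIs in 7965 and 11327 cells. Median depth per cell was 7158.5 and 8757.5 UMIs with acupuncture and 5539 and 6815 UMIs without. Cells above the mitochondrial limit made up 16.0% of dysentery replicate 1 and 7.0%, 7.17% and 5.11% of acupuncture replicates 1 and 2 and dysentery replicate 2. After filtering, 7704, 8567, 6310 and 9816 cells were kept in acupuncture replicates 1 and 2 and dysentery replicates 1 and 2. Library titles set the direction of every comparison, and the treatment field names the opposite group for all 4 libraries, so each sign would turn if that field were right. The study's title names Ptgs2-positive telocytes and M2 macrophages, and the comparisons ask how these cells and their genes differ with acupuncture.

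Macrophage-like cells made up 24.7% ± 2.01 of cells with acupuncture and 8.72% ± 0.709 without (SD, n = 2), a log2 difference of 1.5 ± 0.46 (SE) that did not pass the test (adjusted p = 0.111). With TMM on cell numbers it was 0.90 (adjusted p = 0.282). Mural cells, the pericytes and smooth muscle of vessel walls, made up 0.726% ± 0.185 and 0.164% ± 0.0152 of cells (log2 2.14 ± 0.53, adjusted p = 0.111). Mast cell-like cells, which release histamine, stood at 0.542% ± 0.472 and 0.111% ± 0.0448 (log2 2.25, adjusted p = 0.128). Vascular endothelial-like cells stood at 2.43% ± 0.469 and 1.00% ± 0.0256 (log2 1.28, adjusted p = 0.128). Fibroblast/telocyte-like cells were the most numerous class, at 46.9% ± 6.0 with acupuncture and 53.3% ± 12.8 without (log2 -0.19, adjusted p = 0.780). NK or innate lymphoid cell-like cells were 6.70% of dysentery replicate 1 and 1.43% of dysentery replicate 2, against 1.19% and 1.12% with acupuncture (log2 -1.81, adjusted p = 0.175). T cell-like (log2 -0.41), dendritic cell-like (0.71), monocyte-like (-0.65), neutrophil-like (-0.26) and B cell-like cells (-1.44) had adjusted p of 0.618, 0.438, 0.610, 0.812 and 0.306. The unnamed clusters together held 4.45% ± 1.10 and 13.7% ± 3.90 of cells (log2 -1.62, adjusted p = 0.111). The largest of them, cluster 17, shared leading genes with the dendritic cell-like class. It held 63 and 42 acupuncture cells against 329 and 1398 dysentery cells. Counted with that class, it would turn the sign of the dendritic cell-like difference, and the gap between the unnamed shares rests on it. No class share passed in edgeR (0 classes), and 1 class passed without dysentery replicate 2, namely NK or innate lymphoid cell-like cells.

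**Figure D1:**
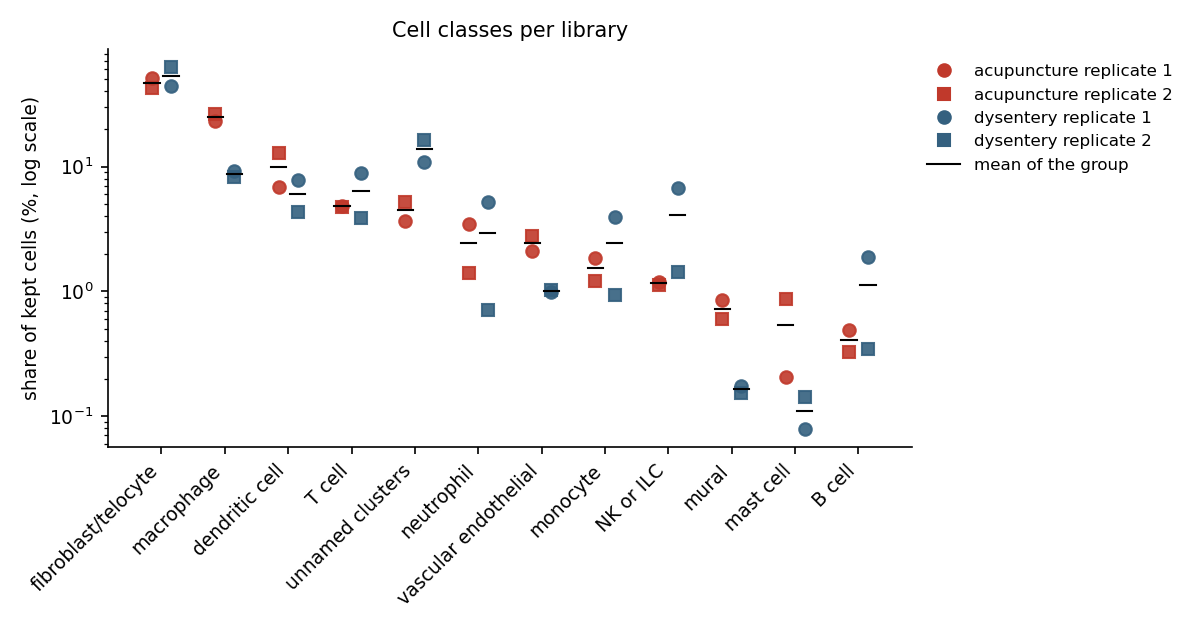
Share of kept cells (percent, log axis) in each cell class, with 1 point per library and horizontal lines at the group mean. Macrophage-like cells were 23.3% and 26.2% of the acupuncture libraries and 9.22% and 8.22% of the dysentery libraries.

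In fibroblast/telocyte-like cells, several cytokines and chemokines were higher with acupuncture. Il6, a cytokine of the acute phase response, rose from 0.444 ± 0.170 to 130 ± 23.6 CPM (SD, n = 2; log2 8.09 ± 0.26 SE, adjusted p = 0.000606). The neutrophil-attracting chemokine Cxcl1 rose from 54.0 ± 42.9 to 1639 ± 677 CPM (log2 4.92 ± 0.68, adjusted p = 0.0290), and Ccl2, which attracts monocytes, rose from 203 ± 75.4 to 1394 ± 46.4 CPM (log2 2.78 ± 0.27, adjusted p = 0.0125). Atf3, a stress-induced transcription factor, rose by 4.53 ± 0.17 on the log2 scale (adjusted p = 0.000994). The other large rises were in Ptx3, a soluble pattern recognition protein (6.03), Cxcl3, another neutrophil attractant (5.95), Nfkbiz, a regulator of NF-kB (4.19), the stress cytokine Gdf15 (4.07) and the transcription factor Nfil3 (4.05). Apod, a lipid carrier, fell by 3.32 ± 0.18 (adjusted p = 0.00196), from 36.9 ± 2.35 to 3.69 ± 0.851 CPM. The B cell chemoattractant Cxcl13 fell by 2.64 ± 0.21 (adjusted p = 0.00787), from 552 ± 146 to 88.7 ± 6.78 CPM. Other large falls were in Olfml2a (-2.45), the guidance cue Slit2 (-2.25) and Duox1, which makes hydrogen peroxide (-1.89). Ighm (-3.24) and Hba-a3 (-2.88), which belong to B cells and red blood cells, also fell.

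Each called gene named in fibroblast/telocyte-like cells had both acupuncture libraries on the same side of both dysentery libraries. The rule required this of the largest rises and falls. It also held for 6969 of the 13150 genes tested in this class, called or not, so it adds little to the calls. Of the 13150 genes tested, 333 changed, 235 higher and 98 lower with acupuncture. The count was 856 in DESeq2, 150 without acupuncture replicate 1, 73 without acupuncture replicate 2 and 830 without dysentery replicate 1, with 369 without dysentery replicate 2. Of 54 called genes that the rule named, 29, 19, 54 and 50 still passed without acupuncture replicates 1 and 2 and dysentery replicates 1 and 2, and none changed sign. The class was made of different clusters in the groups. Cluster 4, led by Col1a1 and with Has1 among its leading genes, held 1160 and 1406 acupuncture cells against 16 and 28 dysentery cells. Cluster 6 held 19 and 4 against 307 and 3064. Within cluster 10, which held at least 447 cells in every library, the log2 difference of Ccl2 was 1.08 ± 0.56 and did not pass (adjusted p = 0.388). Atf3 (4.30, adjusted p = 0.00245), Il6 (6.25, adjusted p = 0.0158) and Cxcl1 (5.71, adjusted p = 0.0158) passed there, and Ptgs2 did not (2.67 ± 0.58, adjusted p = 0.0689). With doublets kept, 51 of the 54 passed and 1 moved by over 1.5 times.

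Ptgs2, the inducible enzyme of prostaglandin synthesis, stood at 493 ± 220 CPM with acupuncture and 61.7 ± 39.9 CPM without (SD, n = 2). Its log2 difference of 2.99 ± 0.54 did not pass the test (adjusted p = 0.0541). Both acupuncture libraries stood above both dysentery libraries, but such separation was common among the genes tested. Over the 4 fits that each left out 1 library the difference was 2.45 to 3.88, and the adjusted p was 0.0882 and 0.215 without acupuncture replicates 1 and 2. Ptgs2 passed without dysentery replicate 1 (0.00607) or dysentery replicate 2 (0.00398) and with DESeq2 (0.00500), and its adjusted p ran from 0.00101 to 0.215 over all alternatives. Cd34 (log2 0.26 ± 0.10, adjusted p = 0.245) and Pdgfra (0.17 ± 0.16, adjusted p = 0.611), the surface markers used for telocytes, did not pass. Ptges, the synthase next in the pathway, had no row under its symbol. Of 14 measured genes of prostaglandin synthesis and response, 0 passed over all genes tested in edgeR and 6 passed adjusted over the list alone, and the median was -0.31 (adjusted p = 0.278, and adjusted p = 0.533 with an estimated correlation).

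Among cells with UMIs of both Cd34 and Pdgfra, thinned to 2000 UMIs, 19.2% ± 10.0 had a Ptgs2 UMI with acupuncture and 10.4% ± 7.26 without (SD, n = 2). The difference of 8.85 percentage points was within the spread between libraries (two-sided exact permutation p = 0.667, with 1 in 3 the smallest possible). The shares were 12.1% (95% Clopper-Pearson interval 8.99 to 15.9) of 371 cells and 26.3% (20.5 to 32.8) of 209 cells with acupuncture. In the dysentery libraries they were 5.23% (2.42 to 9.70) of 172 cells and 15.5% (11.7 to 20.0) of 316 cells. Over all fibroblast/telocyte-like cells the shares were 21.3% ± 9.01 and 8.62% ± 5.66. T cell-like cells, which should lack Ptgs2, gave 0.385% ± 0.544 and 0.0962% ± 0.136 at the same depth. Thinning to 1000 UMIs left a difference of 0.87 points and no thinning 19.2 points, and leaving out 1 library gave 1.76 to 15.9 points.

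**Figure D2:**
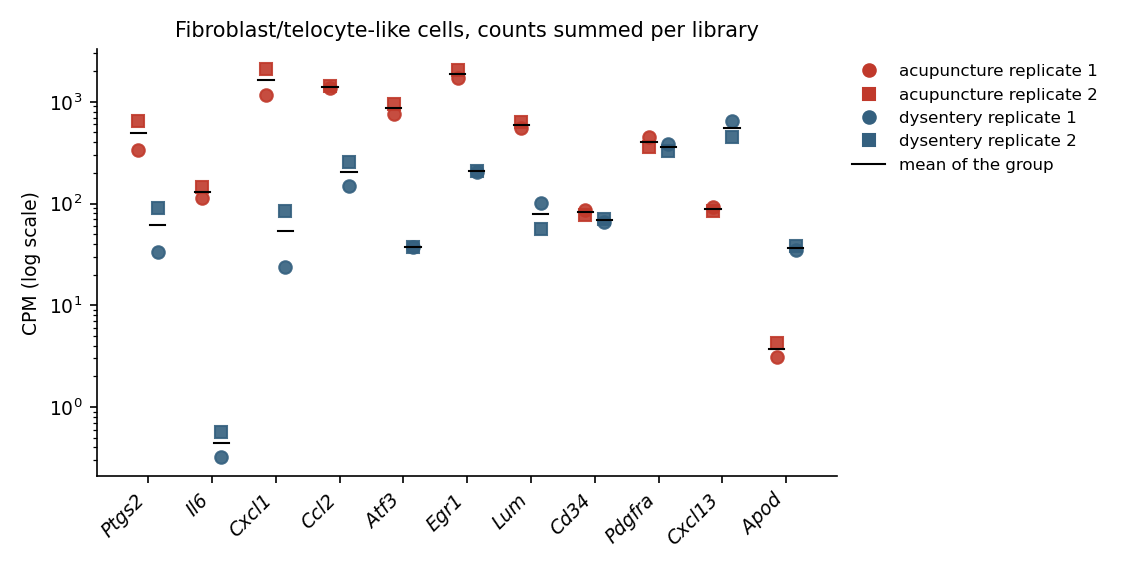
Levels of named genes in fibroblast/telocyte-like cells (CPM, log axis), with 1 point per library and horizontal lines at the group mean. Il6 was 130 CPM on average with acupuncture and 0.444 CPM without, and Cd34 82.1 and 68.6 CPM.

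Immediate early genes, the first to be transcribed after a stimulus, formed the list with the most called members in fibroblast/telocyte-like cells: 18 of 27 rose and 0 fell, with a median of 1.83 (adjusted p = 2.81e-19, and adjusted p = 0.533 with an estimated correlation). Atf3, Egr1 (3.17) and Egr2 (3.08) had the largest rises among them, and 24 passed adjusted over the list alone. Of 23 NF-kB response genes, 9 rose, Nfkbiz, Cxcl1 and Ccl2 among them (median 0.69, adjusted p = 1.03e-05, and adjusted p = 0.533 with an estimated correlation), with 14 adjusted over the list alone. Heat shock genes, which encode chaperones, rose in 7 of 19 cases, with Dnajb4 at 2.19, Dnajb1 at 1.5 and Hsp90aa1 at 1.5 (adjusted p = 1.20e-09, and adjusted p = 0.533 with an estimated correlation). Of 21 inflammatory cytokines and chemokines, 6 rose, including Il6, Ccl20 (6.78) and Cxcl3, and Cxcl13 fell (adjusted p = 0.0128, and adjusted p = 0.533 with an estimated correlation). Collagens and fibrillar matrix genes had 2 rises in 34, the collagen-binding proteoglycan Lum (2.93) and elastin, Eln (1.43), with a median of 0.45 (adjusted p = 0.00116, and adjusted p = 0.533 with an estimated correlation). Matrix proteases and inhibitors had 5 rises and 1 fall in 27, with the protease inhibitor Serpine2 at 2.48 and the hyaluronan synthase Has1 at 2.27 (adjusted p = 0.0354, and adjusted p = 0.533 with an estimated correlation). M2 macrophage genes had 4 rises in 22, among them Il10 (3.17, at 3.94 ± 1.60 CPM), Pf4 (1.68) and Socs1 (1.03) (adjusted p = 0.00449, and adjusted p = 0.533 with an estimated correlation). Il10 stood at 766 ± 123 and 135 ± 94 CPM in macrophage-like cells, and, looked up after these values were seen, was also higher in T cell-like (2.54, adjusted p = 0.00562) and dendritic cell-like cells (2.37, adjusted p = 0.00430). Macrophage markers in the fibroblast/telocyte-like sums had positive log2 values for 8 of 11 genes, with a median of 0.48 (adjusted p = 0.359). Whether RNA of the M2 genes came from the fibroblast/telocyte-like cells themselves was not tested.

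Lower as lists were acute phase, complement and antimicrobial genes, where 2 of 22 fell, Lbp (-1.66) among them (median -0.36, adjusted p = 0.0111, and adjusted p = 0.533 with an estimated correlation). Lipid handling and lysosome genes had 1 fall in 23, which was Lpl at -0.83 (adjusted p = 0.00275, and adjusted p = 0.533 with an estimated correlation). Antigen presentation genes had 0 of 17 past the threshold in edgeR (median -0.48, adjusted p = 0.00477, and adjusted p = 0.533 with an estimated correlation). Ribosomal protein genes had 0 of 52 past the threshold (median -0.16, adjusted p = 0.00168, and adjusted p = 0.753 with an estimated correlation). Cell cycle genes were instead higher as a list, with 0 of 21 past the threshold (median 0.29, adjusted p = 0.0445, and adjusted p = 0.659 with an estimated correlation). Lists that did not pass were M1 macrophage genes (4 rises in 19, among them Socs3 at 2.22 and Cxcl10 at 2.36, adjusted p = 0.0704) and glucocorticoid response genes (4 rises and 3 falls in 23, with Mt1 at 2.69 and Fkbp5 at 2.24, adjusted p = 0.170). Interferon response genes had Ifit2 higher (0.69) and Herc6 lower (-1.58) among 24 (adjusted p = 0.416). Mechanical stretch genes had 2 rises in 28, Ccn1 (2.17) and Myl9 (2.19), with an adjusted p of 0.320. Tissue niche signals had 4 rises and 1 fall in 32, with Bmp2 at 1.74, Fgf18 at 0.96 and Chrdl1 at -1.08 (adjusted p = 0.481). Signals from stroma to macrophages had 3 rises and 1 fall in 29, with Ccl7 at 1.71 and Cd200 at 0.90 (adjusted p = 0.320). Hypoxia and glycolysis genes had 2 rises and 1 fall in 28, with Hk2 at 2.09, Higd1a at 1.15 and Ndrg1 at -0.66 (adjusted p = 0.0704), and oxidative phosphorylation genes had 0 of 37 past the threshold (adjusted p = 0.783).

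Among markers of other cells in fibroblast/telocyte-like sums, skeletal muscle had 2 rises in 5 (adjusted p = 0.00928, and adjusted p = 0.533 with an estimated correlation), Acta1 with 168 and 71 UMIs against 3 and 3, and Ckm with 48 and 32 against 0 and 1. The fibroblast markers had Lum higher among 12 (median 0.37, adjusted p = 0.0452, and adjusted p = 0.533 with an estimated correlation). Markers of platelets and erythrocytes (adjusted p = 0.20), adipocytes (0.973), keratinocytes (0.703), mast cells (0.666), neutrophils (0.783), T cells (0.783), B cells (0.584), macrophages (0.359) and vascular endothelium (0.569) did not pass as lists. Calls ended without acupuncture replicate 1 for antigen presentation (adjusted p = 0.0567), proteases (0.0575) and ribosomal proteins (0.443). Without acupuncture replicate 2 they ended for proteases (0.205), the cell cycle (0.324) and fibroblast markers (0.292). Without dysentery replicate 1 they ended for acute phase genes (0.637), lipid handling (0.0620) and fibroblast markers (0.131), and without dysentery replicate 2 for cytokines and chemokines (0.383), ribosomal proteins (0.271) and the cell cycle (0.265). With doublets kept they ended for acute phase genes (0.229), lipid handling (0.132) and fibroblast markers (0.0821). With a replicate block they ended for proteases (0.0897). At a mitochondrial limit of 10% they ended for the cell cycle (0.0856) and fibroblast markers (0.0558), and at Leiden resolution 2 for the cell cycle (0.0679). With shallow clusters left out, an alternative chosen after seeing the data, they ended for proteases (0.0638), the cell cycle (0.0672) and fibroblast markers (0.0672).

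In macrophage-like cells, the neutrophil-attracting chemokines Cxcl1 and Cxcl2 were higher with acupuncture and the monocyte receptor Ccr2 was lower. Cxcl2 rose from 575 ± 168 to 4875 ± 2067 CPM (SD, n = 2; log2 3.08 ± 0.38 SE, adjusted p = 0.0381), and Cxcl1 rose by 3.66 ± 0.51 (adjusted p = 0.0457). Gdf15 rose from 112 ± 19.5 to 969 ± 179 CPM (log2 3.12 ± 0.22, adjusted p = 0.0110), and Gadd45b, a gene of the stress response, rose by 2.62. Other large rises were in Iqcn (5.04), Ccdc152 (3.51), the transcriptional repressor Tgif2 (2.89) and Tmem88 (2.53). Ccr2, the receptor for Ccl2 that marks monocytes leaving the blood, fell by 2.66 ± 0.16 (adjusted p = 0.00911), from 70.9 ± 5.00 to 11.3 ± 1.63 CPM. Lsp1, a leukocyte actin-binding protein (-2.95), the cystatin Cst7 (-2.89), the protease Napsa (-2.75), Hopx (-2.38), complement C3 (-2.36), S100a6 (-2.25) and Tppp3 (-2.10) also fell.

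The M2 marker receptors Mrc1 (log2 0.36 ± 0.27, adjusted p = 0.511) and Cd163 (0.56 ± 0.31, adjusted p = 0.389) did not pass in macrophage-like cells. Il10, an anti-inflammatory cytokine, stood at 766 ± 123 CPM with acupuncture and 135 ± 94 CPM without (log2 2.50 ± 0.49, adjusted p = 0.0847). It passed without dysentery replicate 1 (0.000888) or dysentery replicate 2 (3.63e-05) and in DESeq2 (0.0195), over a range up to 0.296 without acupuncture replicate 2. Tgfb1 (0.24, adjusted p = 0.371), Ptger4, a prostaglandin E receptor (0.20, adjusted p = 0.827), and the M1 genes Nos2 (0.75, adjusted p = 0.773), Il1b (0.26, adjusted p = 0.659) and Tnf (1.28, adjusted p = 0.177) did not pass either. Il1b turned to -0.18 without acupuncture replicate 2, Ptger4 to -0.15 without dysentery replicate 1 and Nos2 to -0.30 without dysentery replicate 2. Arg1 had 2, 7, 25 and 3 UMIs and Ptger2 1, 1, 0 and 0 in acupuncture replicates 1 and 2 and dysentery replicates 1 and 2, too few to test. Of thinned macrophage-like cells, 49.8% ± 8.16 had an Il10 UMI with acupuncture and 15.3% ± 8.91 without, against 2.42% ± 0.161 and 0.473% ± 0.125 of T cell-like cells. B cell-like cells gave 6.29% ± 3.23 and 1.32% ± 1.86, and vascular endothelial-like cells 0.926% ± 1.31 and 0%.

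**Figure D3:**
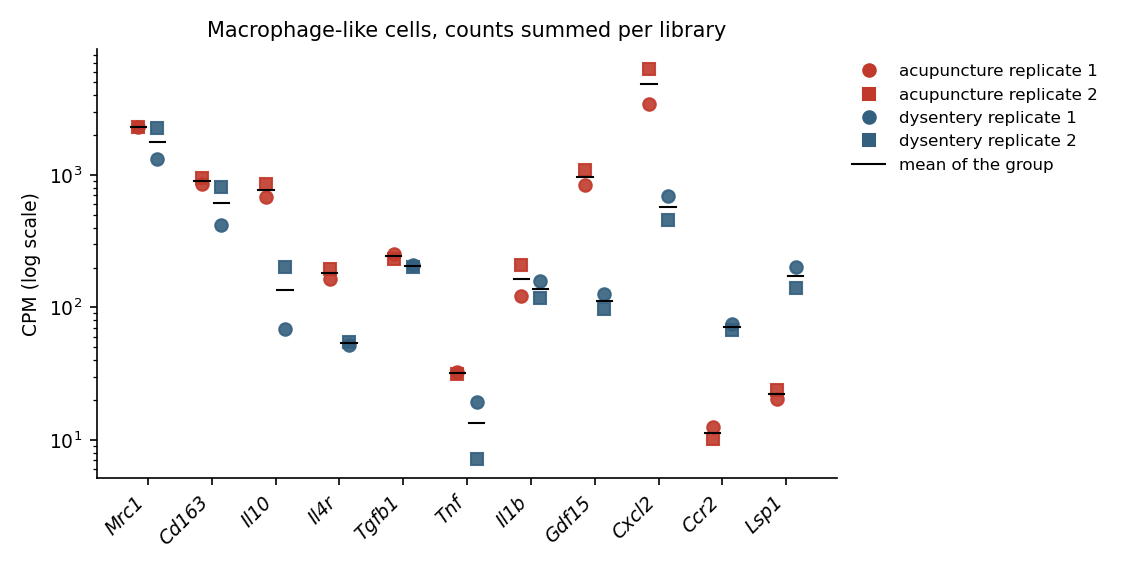
Levels of named genes in macrophage-like cells (CPM, log axis), with 1 point per library and horizontal lines at the group mean. Ccr2 was 11.3 CPM on average with acupuncture and 70.9 CPM without, and Il10 766 and 135 CPM.

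Of 11071 genes tested in macrophage-like cells, 120 changed, 75 higher and 45 lower. The count was 501 in DESeq2, 53 and 12 without acupuncture replicates 1 and 2, 638 and 911 without dysentery replicates 1 and 2, and 36 with doublets kept. Without dysentery replicate 2 most calls were lower (381 higher and 530 lower). Of 37 called genes that the rule named, 21, 4, 37 and 37 still passed without acupuncture replicates 1 and 2 and dysentery replicates 1 and 2, and none changed sign. With doublets kept, 18 of the 37 passed and 2 moved by over 1.5 times. With a replicate block, 0 of the 37 passed. Cluster 2 held 1117 and 1638 acupuncture cells against 11 and 36 dysentery cells, and cluster 28, led by Mmp12, held 118 cells of dysentery replicate 1 against 11, 3 and 3 in the others. Without cluster 28, an alternative chosen after seeing the data, 546 genes passed.

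M2 genes as a list were higher in macrophage-like cells (median 0.55, adjusted p = 0.000263, and adjusted p = 0.490 with an estimated correlation). Of 23 measured, 1 rose, the interleukin receptor Il4r (1.76 ± 0.14, adjusted p = 0.0142), and 6 passed adjusted over the list alone. The M2 median was 0.36 without acupuncture replicate 1 and 0.34 without dysentery replicate 1, and the list still passed in each. M1 genes were also higher as a list (median 0.54, adjusted p = 0.0173, and adjusted p = 0.490 with an estimated correlation), with 1 rise in 20, the cytokine signalling inhibitor Socs3 (2.40), and 9 adjusted over the list alone. The M1 call ended without acupuncture replicate 2 (median 0.28, adjusted p = 0.0807), without dysentery replicate 2 (0.32, 0.135) and with doublets kept (adjusted p = 0.0552). Immediate early genes had 8 rises in 27, among them Gadd45b, Socs3 and Ier3 (2.01), with a median of 1.51 (adjusted p = 1.41e-14, and adjusted p = 0.490 with an estimated correlation). NF-kB response genes had 2 rises in 23, Bcl3 (2.44) and Cxcl1 (median 0.81, adjusted p = 0.000263, and adjusted p = 0.563 with an estimated correlation). Heat shock genes had 0 of 18 past the threshold in edgeR (median 0.42, adjusted p = 0.000929, and adjusted p = 0.668 with an estimated correlation). The antiviral genes Mx1 (1.70) and Irf7 (1.45) rose among 25 interferon response genes (median 0.21, adjusted p = 0.0343, and adjusted p = 0.490 with an estimated correlation).

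Matrix and stromal genes stood lower in macrophage-like sums of acupuncture. Fibroblast markers had 2 falls in 11, Serpinf1 (-1.12) and Pi16 (-1.01), with a median of -0.92 (adjusted p = 0.000216, and adjusted p = 0.490 with an estimated correlation). Collagens and fibrillar matrix genes had 0 of 23 past the threshold over all genes tested in edgeR and 15 adjusted over the list alone (median -0.95, adjusted p = 3.74e-05, and adjusted p = 0.490 with an estimated correlation). Matrix proteases and inhibitors had Mmp2 lower (-1.44) among 19 (median -1.03, adjusted p = 0.0242, and adjusted p = 0.490 with an estimated correlation). Tissue niche signals had Igfbp6 lower (-1.76) and Igfbp4 higher (2.10) among 14 (median -0.68, adjusted p = 0.0124, and adjusted p = 0.490 with an estimated correlation). Acute phase, complement and antimicrobial genes had 4 falls and 1 rise in 19, with C3, C4a (-2.02) and C4b (-1.79) lower (median -0.70, adjusted p = 0.0311, and adjusted p = 0.490 with an estimated correlation). Antigen presentation genes had 0 of 18 past the threshold (median -0.40, adjusted p = 0.0124, and adjusted p = 0.678 with an estimated correlation). Skeletal muscle markers were higher, with Acta1 called (2.72) among 5 (adjusted p = 0.00296, and adjusted p = 0.490 with an estimated correlation), and B cell markers lower with 0 of 5 past the threshold (median -0.66, adjusted p = 0.0462, and adjusted p = 0.490 with an estimated correlation).

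Among the lists that did not pass in macrophage-like cells, cytokines and chemokines had Cxcl1 and Cxcl2 higher and Cxcl12 (-1.58) and Il33 (-1.51) lower among 18 (adjusted p = 0.236). Glucocorticoid response genes had 3 rises and 1 fall in 22, with Mt1 at 2.23, Klf9 at 2.05 and Cdkn1a at 1.80; their median was -0.04 and their mean 0.26 (adjusted p = 0.349). Signals from stroma to macrophages had 3 falls in 25, which were C3, Cxcl12 and Il33 (adjusted p = 0.534). Lipid handling and lysosome genes had 2 falls in 23, the lipases Lpl (-2.04) and Lipa (-1.70), with an adjusted p of 0.534. No member passed in edgeR for prostaglandin genes (0 of 12, adjusted p = 0.278), mechanical stretch genes (0 of 16, 0.553), hypoxia and glycolysis (0 of 26, 0.0526), oxidative phosphorylation (0 of 37, 0.957), ribosomal proteins (0 of 52, 0.905) or the cell cycle (0 of 15, 0.435). Nor did markers of platelets and erythrocytes (adjusted p = 0.278), adipocytes (0.852), mast cells (0.554), neutrophils (0.476), T cells (0.665), macrophages (0.665) or vascular endothelium (0.824), and keratinocyte markers had 2 measured members, too few to test. Calls ended without acupuncture replicate 1 for proteases (adjusted p = 0.0860), niche signals (0.108) and B cell markers (0.0785). Without acupuncture replicate 2 they ended for acute phase genes (0.0720), proteases (0.258), niche signals (0.602) and B cell markers (0.0720). Without dysentery replicate 1 they ended for antigen presentation (0.215) and proteases (0.342), and without dysentery replicate 2 for heat shock (0.121), interferon response (0.133), niche signals (0.139) and B cell markers (0.112). With sums thinned to the smallest library they ended for niche signals (median -0.14, adjusted p = 0.753), proteases (0.208), interferon response (0.0915) and B cell markers (0.340). With doublets kept they ended for acute phase genes (0.0558) and B cell markers (0.0529), and with no filter for interferon response (0.0898) and B cell markers (0.105). B cell markers also ended at Leiden resolution 2 (0.0808), and without cluster 28 niche signals (0.238) and B cell markers (0.0964) did.

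**Figure D4:**
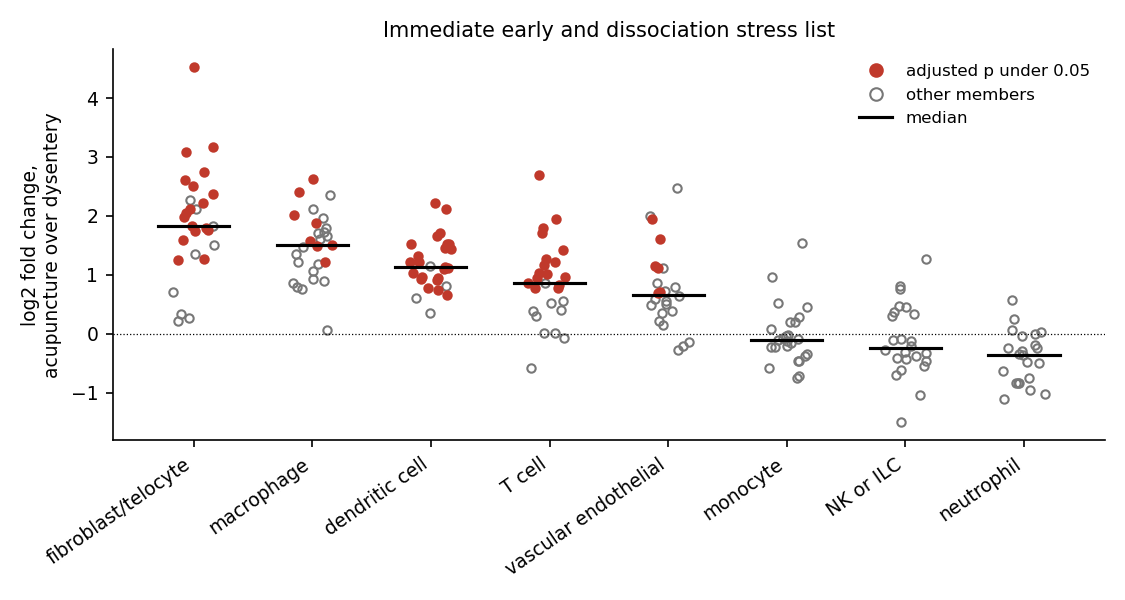
Log2 fold change (acupuncture minus dysentery) of each measured immediate early gene in each tested class, with 1 point per gene, filled where it passed the threshold of 0.05, and lines at the median. The median ran from 1.83 in fibroblast/telocyte-like and 1.51 in macrophage-like cells to -0.36 in neutrophil-like cells.

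Both main classes shared 30 genes that were called higher, where 1.37 would be expected from the separate counts among 10633 genes tested in both, and 2 called lower (0.291 expected). None was called in opposite directions (0 genes). Gdf15, Mt1, Socs3, Gadd45b, Bcl3, Cxcl1 and Il4r were among the shared rises, and Lpl was a shared fall. The same libraries gave both classes, so these counts are not independent. The change itself differed between the classes for 214 of 13555 genes by the interaction test, 93 with a higher and 121 with a lower log2 change in macrophage-like cells. The change of Il6 was lower in macrophage-like cells, by a difference of -5.75, as was that of Atf3 (-2.82), while Ptgs2 (-1.81, adjusted p = 0.224) and Cxcl1 (-1.58, adjusted p = 0.237) did not pass. The number fell to 0 and 5 without acupuncture replicates 1 and 2 and rose to 508 and 835 without dysentery replicates 1 and 2.

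In the other tested classes, the calls of the single classes added up to 1569. A gene called in several classes was counted once for each, and 1133 of the calls were in dendritic cell-like cells. T cell-like cells had 183 genes higher and 54 lower of 8979 tested, with Il17f (4.95 ± 0.62, adjusted p = 0.00370) and Il22 (3.37 ± 0.59, adjusted p = 0.0160), cytokines of type-3 immunity, higher. Ifi27, an interferon-induced gene, fell in T cell-like cells by 3.17 ± 0.17 (adjusted p = 2.44e-05), as did Ace (-2.15) and Lpl (-2.09). With doublets kept, Lpl turned to 0.14. NK or innate lymphoid cell-like cells had 24 genes higher and 16 lower of 6168, with Ifi27 (-4.30 ± 0.26, adjusted p = 0.000139) and the chemokine-scavenging receptor Ackr3 (-3.13) lower and Gprin3 (3.84) higher. The class was made of different clusters: cluster 29 held 118 cells of dysentery replicate 1 against 9, 0 and 2 in the others, and cluster 30 held 22 and 12 acupuncture cells against 141 and 78 dysentery cells. Cxcl1 was called higher in 7 of 8 tested classes, at 33.3 ± 20.9 CPM with acupuncture in T cell-like (3.51) and 32.6 ± 18.6 CPM in NK or innate lymphoid cell-like cells (3.40), against 1639 and 2680 CPM in fibroblast/telocyte-like and macrophage-like cells. Cpne4 had 0 and 0 UMIs with acupuncture and was at least 10.2-fold lower, against a floor of 3 counts over the group, and Slc27a2 had 18 and 15 UMIs with acupuncture and 2 and 0 without. Dendritic cell-like cells had 761 genes higher and 372 lower of 10440, with the growth factor Areg (3.70), Ptpn13 (3.62) and Vps37b (3.54) higher and Plpp7 (-2.74), Thy1 (-2.70) and Tpm2 (-2.52) lower. An unnamed cluster shared leading genes with the dendritic cell-like class, whose bounds are therefore uncertain. Within the class, cluster 13 held 480 and 992 acupuncture cells against 154 and 138 dysentery cells, and cluster 25 held 21 and 31 against 260 and 222. Monocyte-like cells had 4 genes higher and 23 lower of 6858, with the chemokine Ccl7 higher (3.61 ± 0.26, adjusted p = 4.25e-05) and Cd8a (1.65) higher and Ddr2 (-3.41) and Ccl5 (-3.33) lower, and Cxcl13 with 1 and 0 UMIs against 30 and 5. Vascular endothelial-like cells had 90 genes higher and 42 lower of 6952: Ccl21 was at least 53.2-fold, Acta2 at least 18.3-fold and Il6 at least 11.3-fold higher, each with 0 UMIs in both dysentery libraries. These bounds rest on means of unequal libraries for Ccl21 (157 ± 152 CPM, 42 and 318 UMIs) and Acta2 (54.0 ± 49.3 CPM, 75 and 23 UMIs). With doublets kept the log2 differences were 0.54 for Ccl21 (adjusted p = 0.943), 1.03 for Acta2 (0.597) and 7.82 for Il6 (0.0688), and none passed. Genes of fibroblasts rose in the same sums, Col3a1 by 2.36 (adjusted p = 0.00123), Col1a1 by 1.70 and Col1a2 by 1.35, and Il6 stood at 33.3 CPM there against 130 CPM in fibroblast/telocyte-like cells. Chrna1 (-3.22) and Aqp7 (-2.80) fell in them, and Scgb1a1 had 2 and 1 UMIs against 13 and 19. Neutrophil-like cells had 0 of 3975 genes past the threshold in edgeR, 425 at an unadjusted p under 0.05 and 30 in DESeq2.

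Of 6 named genes, 1 still passed in T cell-like cells without dysentery replicate 2 and 1 in NK or innate lymphoid cell-like cells without acupuncture replicate 2, and of 5 in monocyte-like cells 1 passed without dysentery replicate 1. With doublets kept 0 of 6 passed in NK or innate lymphoid cell-like, 3 of 6 in T cell-like, 1 of 6 in monocyte-like and 1 of 5 in vascular endothelial-like cells. DESeq2 kept 2 of 6 in vascular endothelial-like and 2 of 5 in monocyte-like cells, and thinned sums 1 of 5 in NK or innate lymphoid cell-like and 1 of 2 in vascular endothelial-like cells. Leiden resolution 2 kept 3 of 6 in T cell-like and 2 of 6 in monocyte-like cells, and components centred per library 2 of 6 in monocyte-like cells. In dendritic cell-like cells 3 of 4 passed at a mitochondrial limit of 10% and 4 of 6 with the unnamed cluster joined, and 2 moved by over 1.5 times in each, with 1 at Leiden resolution 2. Moves of that size were also seen with doublets kept, for 3 genes in T cell-like, 1 in NK or innate lymphoid cell-like, 2 in monocyte-like and 2 in vascular endothelial-like cells. In T cell-like cells 2 moved so at Leiden resolution 2 and 1 without acupuncture replicate 2, and without dysentery replicate 1 so did 1 in NK or innate lymphoid cell-like and 1 in monocyte-like cells. The joint count was 3202 and 2413 without acupuncture replicates 1 and 2, 963 at Leiden resolution 2 and 414 with components centred per library, where the dendritic cell-like class (1133 calls) fell below the minimum number of cells and was not tested.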

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

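The test of depth for the immediate early list was chosen only after the result was seen. For 31 of 122 named genes, the change with acupuncture differed between fibroblast/telocyte-like and macrophage-like cells by the interaction test of edgeR. Of these, 30 are given here. Values are the log2 change in macrophage-like cells minus that in fibroblast/telocyte-like cells. The number of genes passing fell sharply when either acupuncture library was left out. Such fits take their spread from the dysentery libraries alone, so this does not show whether the differences themselves rest on both acupuncture libraries.

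Genes that rose with acupuncture in fibroblast/telocyte-like cells and had a smaller change in macrophage-like cells were Il6 (-5.75), Atf3 (-2.82), Nfkbiz (-1.81), Egr2 (-1.60), Ccn1 (-1.37) and Bmp2 (-1.19). Genes with a larger rise in macrophage-like cells were Iqcn (3.33), Klf9 (1.72), Irf7 (1.52), Cdkn1a (1.35), Ccdc152 (1.23) and Il4r (1.09). Genes that fell in fibroblast/telocyte-like cells and less or not in macrophage-like cells were Apod (3.73), Herc6 (2.15), Ighm (1.82) and Duox1 (1.80). Genes that fell in macrophage-like cells and less or not in fibroblast/telocyte-like cells were C3 (-3.44), Lsp1 (-3.39), Tppp3 (-2.05), S100a6 (-1.75), Pi16 (-1.50), Hopx (-1.50), C4a (-1.33), C4b (-1.27), Mmp2 (-1.26), Lipa (-1.24) and Lpl (-1.19). Pi16 is a fibroblast marker, and C4b was among the leading genes of fibroblast clusters 11 and 12. For such genes, free fibroblast RNA, taken up below, was not told apart from a change in macrophages. Fabp4 (-4.63) and Hbb-b1 (2.44) differed between the classes without passing in either, and Cd200 (-2.12) passed in fibroblast/telocyte-like cells alone. In macrophage-like cells Fabp4 had 3627 UMIs in dysentery replicate 1, 322 in dysentery replicate 2 and 130 and 179 with acupuncture. Hbb-b1, a gene of red blood cells, had 171 and 789 UMIs there with acupuncture and 65 and 11 without.

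Immediate early genes were higher with acupuncture in both main classes, with medians of 1.83 and 1.51. If all cells of the acupuncture libraries had been handled or held longer, each class should show the rise, but the median was -0.36 in neutrophil-like, -0.24 in NK or innate lymphoid cell-like and -0.10 in monocyte-like cells, against 1.14 in dendritic cell-like, 0.86 in T cell-like and 0.66 in vascular endothelial-like cells. With the sums thinned to the smallest library, the lower of the medians was 1.48. Random thinning of sums leaves ratios nearly unchanged, so it cannot decide on depth. Within fibroblast cluster 10, which held at least 447 cells in every library, the median was 1.32, with 7 of 25 members called. That argues against a different mix of fibroblast clusters as the whole cause in fibroblast/telocyte-like cells, but the mix may add to the rise. The mix of macrophage clusters was not tested. A response to digestion that differs between cell types, and that took longer or ran warmer in 1 group, was not tested and stays open, since no dates or handling times were given. An effect of acupuncture that acts on some cell types may also underlie the pattern, as a hypothesis found and tested on the same data.

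Fibroblast markers were lower in macrophage-like sums of acupuncture, with a median of -0.92. The median of the same markers was below -0.3 in all 5 other immune classes, at -0.33 in dendritic cell-like, -0.51 in T cell-like, -0.60 in NK or innate lymphoid cell-like, -1.21 in monocyte-like and -1.77 in neutrophil-like cells, and 0.37 in fibroblast/telocyte-like cells themselves. In vascular endothelial-like cells it was 0.93, with 3 of 11 markers called higher. In dendritic cell-like cells 2 of 12 markers were called higher in edgeR, Pi16 (0.55, adjusted p = 0.0162) among them. The 1 called lower there was Dcn (-1.02, adjusted p = 0.0472). Dcn was also lower in NK or innate lymphoid cell-like cells (-1.18, adjusted p = 0.0432), and Pi16 was at 0.23 in T cell-like cells. Less free fibroblast RNA in the acupuncture libraries thus remains a candidate explanation for the medians of the immune classes. The falls of Dcn go with it, but the values of endothelial cells and of Pi16 in dendritic cell-like cells go against it. A change in the macrophages themselves was not tested and stays open.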

How the results depend on the processing

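Tests that left out shallow fibroblast clusters, left out cluster 28, joined an unnamed cluster to the dendritic cell-like class or used cells other than fibroblasts as the denominator were chosen after the data were seen. The labels do not say that libraries sharing a replicate number share anything else, and 2 pairs are too few to tell from the data. Deviations of the replicates correlated across genes at -0.012 in macrophage-like cells to 0.15 in fibroblast/telocyte-like cells, and above 0.1 in 4 of 8 classes, and Csn1s1 was higher in replicate 1 of both groups. The prostaglandin list and the macrophage-like share stayed on the same side of the threshold under every alternative run, though the share had a log2 difference of 0.90 with TMM on cell numbers, against 1.5. Where a library was left out, its group had 1 library, which is assumed to vary like the other group. For the other results below the cause was not tested, except that no filter tests more genes and fits without a library rest on fewer samples.

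Genes changed in fibroblast/telocyte-like cells numbered 333, and 856 with DESeq2, 842 with no filter, 685 with a replicate block and 73 to 830 with 1 library left out. Genes changed in macrophage-like cells numbered 120, and 501 with DESeq2, 1334 with no filter, 1 with a replicate block, 36 with doublets kept, 546 without cluster 28 and 12 to 911 with 1 library left out. With the replicate block 0 of 37 called named genes passed in macrophage-like cells, and 54 of 54 in fibroblast/telocyte-like cells. The share of calls that were higher moved by more than 10 percentage points in fibroblast/telocyte-like cells (235 higher, 98 lower) with DESeq2 (510 and 346) and without acupuncture replicate 1 (128 and 22), acupuncture replicate 2 (59 and 14) or dysentery replicate 2 (220 and 149). In macrophage-like cells (75 and 45) it did so without acupuncture replicate 2 (6 and 6), with the block (0 and 1) and without dysentery replicate 2 (381 and 530), where most calls were lower. For genes that differed between the main classes (93 and 121) it did so with doublets kept (29 and 76). In the other classes together 1569 genes became 3811 with no filter, 2610 with a replicate block, 963 at Leiden resolution 2, 414 with components centred per library, where the dendritic cell-like class had too few cells to test, and 1316 to 3202 with 1 library left out. Genes that differed between the main classes numbered 214, and 722 with no filter, 105 with doublets kept, 78 with sums thinned and 0 to 835 with 1 library left out.

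Ptgs2 passed the threshold in DESeq2 (log2 2.99), with no filter (3.0), with a replicate block (3.09), with doublets kept (2.96) and with sums thinned (3.0), and lay between 2.45 and 3.88 with 1 library left out. Its share among Cd34+Pdgfra+ cells differed by 0.87 points at 1000 UMIs per cell and 19.2 points with no thinning. All 28 list calls ended with an estimated correlation (0 left), including M2 (0.55) and M1 (0.54) in macrophage-like cells. Camera then rests on the few libraries, so hardly any list could pass. Fibroblast markers in macrophage-like cells had an estimated correlation of -0.0761 and still went to an adjusted p of 0.490 in camera. These losses therefore do not tell whether correlation between genes ended the calls. M1 also missed the threshold with doublets kept (0.44) and lay between 0.28 and 0.79 with 1 library left out. Class shares past the threshold numbered 0 to 1 with 1 library left out.

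Among named genes, 10 values turned sign, and of the genes concerned Lpl in T cell-like cells had passed the threshold. With 1 library left out, the range was -0.78 to 0.36 for Cfd and -2.21 to 0.0144 for Cd3e in fibroblast/telocyte-like cells. In macrophage-like cells it was -0.18 to 0.59 for Il1b, -0.15 to 0.71 for Ptger4, -0.98 to 0.0278 for Krt8 (0.00396 without acupuncture replicate 2), -0.14 to 1.54 for Cma1 and -0.30 to 6.61 for Nos2. With doublets kept Cfd was 1.16 and Lpl in T cell-like cells 0.14. Over the other alternatives 1551 values for named genes kept their side of the threshold, 116 lost it and 56 gained it, and with 1 library left out 456 kept it, 141 lost it and 27 gained it. For the 26 list calls other than M2 and M1 in macrophage-like cells, 239 values kept it and 47 lost it, and 79 and 25 with 1 library left out. The smallest sums were 403397 UMIs in endothelial and 252996 UMIs in neutrophil-like cells.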

Other observations

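The genes in this part were chosen after their values were seen. Ifi27, which interferon induces, was lower with acupuncture in several classes: log2 -4.30 in NK or innate lymphoid cell-like, -3.17 in T cell-like, -1.78 in monocyte-like (adjusted p = 0.000867), -1.71 in dendritic cell-like (adjusted p = 0.00466) and -0.84 in vascular endothelial-like cells (adjusted p = 0.00571). In neutrophil-like cells it stood at -2.55 (adjusted p = 0.0519), and in fibroblast/telocyte-like (0.07) and macrophage-like cells (0.06) it did not pass.

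Genes of milk proteins led an unnamed cluster of 83 and 47 cells in the acupuncture libraries and 110 and 15 in the dysentery libraries. Csn1s1, a casein, stood at 1517 and 91.1 CPM in acupuncture replicates 1 and 2 and at 1180 and 61.7 CPM in dysentery replicates 1 and 2, over all deposited cells. Lalba, a subunit of lactose synthase, stood at 285, 39.2, 424 and 20.6 CPM in the same order. Csn2 and Glycam1, also leading genes of that cluster, stood mostly in acupuncture replicate 1. In the same order, Csn2 was at 1234, 2.75, 20.7 and 2.40 CPM and Glycam1 at 911, 0.703, 2.00 and 0.126 CPM. The beta-globin gene Hbb-b1 stood at 1837 and 4729 CPM with acupuncture and 1185 and 295 CPM without. Acta1, of skeletal muscle, stood at 22.3 and 3.61 CPM against 0.396 and 0.113 CPM.

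Genes of the circadian clock also differed. Ciart, a repressor of the clock, rose in fibroblast/telocyte-like (1.83, adjusted p = 0.00943) and macrophage-like cells (2.43, adjusted p = 0.00662), and the clock repressor Nr1d1 rose in macrophage-like cells (2.09, adjusted p = 0.00931). In dendritic cell-like cells Ciart (1.05, adjusted p = 0.00466) and Nr1d1 (1.03, adjusted p = 0.0144) rose too, as did Nr1d1 in T cell-like cells (1.36, adjusted p = 0.00873). A candidate explanation is that the groups were collected at different times of day, which predicts opposite signs for the output genes of the clock and for its positive arm. The output genes were Dbp, Tef, Hlf, Per2, Per3, Nr1d2 and Bhlhe41. The positive arm was taken as Bmal1, Arntl, Npas2, Clock and Cry1, though Cry1 is itself a repressor of the clock. The medians were 0.32 and -0.68 in fibroblast/telocyte-like and 0.59 and -0.44 in macrophage-like cells, so the smaller gap was 0.999, with signs as predicted but sizes short of the 0.5 set for it in each class. Dendritic cell-like cells also had the predicted signs (0.34 and -0.07). There -0.07 was the value of Cry1, between Arntl (-0.42) and Clock (0.48), so it cannot decide on the prediction. In 3 other classes both medians were positive, with 1 to 3 genes measured in the positive arm. They were 0.99 and 0.63 in T cell-like, 0.73 and 0.42 in NK or innate lymphoid cell-like and 0.53 and 0.50 in vascular endothelial-like cells. In NK or innate lymphoid cell-like cells the positive arm was Cry1 alone, which cannot decide on the prediction. Arntl (0.63) and Clock (0.90) in T cell-like and Clock (0.50) in vascular endothelial-like cells had signs against the prediction, but none of them passed in edgeR. Time of day and treatment cannot be told apart here for Ciart and Nr1d1 in the main classes, since no collection times are given.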
